A study of Rattus norvegicus with 12 samples.

How the data were processed

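Liver RNA of 12-week-old Fischer 344 rats was hybridised to 12 Agilent-014879 oligonucleotide arrays, each holding 2 RNAs labelled with Alexa 647 (red) and Alexa 555 (green). Per the labels, the 6 comparisons were intact males with intact females, hypophysectomised with intact males, hypophysectomised with intact females, hypophysectomised males with hypophysectomised females, and hypophysectomised males given growth hormone (GH) 1 or 2 times with untreated hypophysectomised males. Each comparison had 2 arrays with the dyes swapped. RNA was pooled over 3 to 4 livers, with separate pools on the 2 arrays of a dye swap. The 1-injection GH pool (4 livers, taken 30, 60 or 90 min after the injection) and the 2-injection GH pool (5 livers, injections 3 or 4 h apart) were each used on both arrays. Which pool went on which array is not given in the sources used here. The label of 1 array of the 1-injection comparison leaves the hormone out of the sample's description, and its title was used.

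The deposited scanner files hold, per the file headers, mean and local background intensity of 45018 spots in each colour, read with Agilent Feature Extraction 9.1.3.1. The same deposited files hold processed signals, an intensity after background subtraction, detrending and dye normalization by that software, and the log10 ratio of red to green computed from them. Other deposited columns are flags of 0 or 1 for spots well above background, saturated or outlying. The value table of the series, which the authors call a normalized ratio, was found from the values to be the log2 ratio of channel 2 to channel 1, on the scale of the deposited processed signals. No deposited spot was marked saturated. Between 58.4% and 71.1% of the probes were well above background per dye and array, and for arrays their number limits the precision.

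Mean intensities were background-corrected with the normexp method (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with the data.table package (1.17.8). Control spots (1639) and outlying spots had no weight in the loess, and outlying spots were then left out. Ratios were turned to channel 2 over channel 1 by the dyes in the labels, and the spots of a probe were averaged (41012 distinct probes, 263 of them spotted 10 times). A probe was tested in a comparison where at least 1 of its 2 RNAs was well above background on both arrays, 29001 probes in all. A further 5 probes were outliers on both arrays of a comparison and were not tested there.

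A linear model was fitted per probe with limma to all 12 arrays, with 1 coefficient for each of the 6 comparisons and 1 for the dye (5 residual degrees of freedom, prior degrees of freedom 3.08, prior SD 0.101). The comparisons share 1 estimate of the spread because each has 2 arrays. It joins the GH comparisons, with the same GH pool on both arrays of 1 slide, to comparisons of different pools on different slides. For the latter it may be too small. P-values were adjusted by the Benjamini-Hochberg method over the probes tested in a comparison, and a probe was called at an adjusted p under 0.05. The sex dependence of hypophysectomy was the mean of the 2 direct estimates of the difference, and 2 injections were set against 1 through the hypophysectomised male RNA. Dye coefficients were called at 3598 of 29001 probes. Sums of ratios around the loop of 4 RNAs were checked against 0.

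Gene symbols came from a reference table through the probe's accession (10735 probes), the symbol in the files (5571) or a synonym (3726), leaving out a synonym that put a probe described as X-linked on the Y chromosome. The files gave 16156 probes a symbol that is not an accession (16017 of them matched in the table). The other 24856 were not named, 4015 matched ones among them. A gene was represented by its brightest probe over all arrays. Named genes were, per comparison, the 10 with the largest positive and the 10 with the largest negative log2 ratio among those called, with the same direction on both arrays and a symbol that is not an accession or a predicted name. For the sex dependence and for 2 against 1 injections, 6 each way were named. Up to 4 called members per list with the largest change, Y-linked genes and Xist were added, and a member so chosen may be named where it was not called. The value of 1 gene so chosen is not reported here.

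Gene lists came from general knowledge of rat liver. They covered male-biased, female-biased, STAT5-linked, immediate early, IGF and GH receptor, thyroid hormone responsive, glucocorticoid responsive, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, bile acid, drug-metabolising, interferon responsive, acute phase, cell cycle, liver transcription factor, amino acid catabolism and hepatocyte secretory genes. Marker lists covered macrophages, stellate cells, endothelium, bile duct, lymphocytes, erythroid cells, and pancreas with fat. Of the listed genes, 24 of 26 male-biased, 19 of 20 female-biased, 6 of 9 erythroid and 27 of 30 drug-metabolising ones were matched, no Y-linked gene (0 of 6) was, and Xist was found by its probe's description alone. The other lists missed at most 2 genes each. Lists were tested with camera (preset correlation 0.01), adjusted over 25 lists and 8 contrasts. Of these 200 tests 77 were called, 35 up and 42 down. With an estimated correlation 0 were called (smallest adjusted p = 0.225), and fry, which tests whether a list's genes move on balance one way, called 84, of which camera called 57. A list's median, mean and test differed in sign in 0 of the 59 called tests of the 6 comparisons. In 4 of the 59 called tests of the 6 comparisons the medians on the 2 arrays had opposite signs, namely acute phase after 1 injection and acute phase, bile duct, and pancreas with fat between the hypophysectomised sexes. In 22 of the 59, these 4 included, the median on an array lay over 1.5 times from the fitted one. Skeletal muscle (30 of 38 genes on the array) and intestinal epithelium (28 of 30) lists were added after the data were seen.

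Overlaps of calls were set against the number expected for independent calls. All comparisons share 1 variance per probe, so a probe with a small variance is more easily called in each. The expected numbers and Fisher's test leave this out. Comparisons sharing no RNA were tested with Fisher's exact test, and for those sharing RNA the covariance across probes was set beside 100 simulated draws of unchanged groups. The fit was tested on simulated data with the spread of the sex comparison of intact rats, in which it recovered 82.1%, 98.5% and 100% of probes changed 1.5-fold, 2-fold and 4-fold and made 16 false calls (7.88% of calls, above the nominal 5%). In simulated data for 2 injections, camera called 1 of 25 lists, the one shifted by 1 log2 unit. With an estimated correlation that list had a camera adjusted p of 6.73e-05. Probes were drawn independently there, so the simulation cannot show whether the preset correlation holds in the measured data.

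Comparisons, tests, thresholds, lists and the choice of named genes were fixed before the data were examined, as were the alternatives. The alternatives for values were no background correction, the processed signals, the deposited value table, median centring in place of loess, and quantile normalization of average intensity. Those for probes were no filter or a stricter one on dim probes, 1 probe per gene, an adjusted p of 0.01 and a robust trended prior. Those for the model were no dye coefficient, 1 coefficient per RNA group, the arrays of a comparison alone, replicate or slide blocks, and leaving out each array. Alternatives chosen after seeing the data are named with their values. The 3 slides were scanned in separate sessions. Slide 1 held the 4 GH arrays, and slides 2 and 3 held the first and second arrays of the other comparisons, so that the value within slide 2 or 3 is a single array. Dye effects for each slide were not estimable, and the slide block gave slide 1 its own dye coefficient and the other slides a shared one with a shift between them, as redefined before its counts were seen. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Groups of 2 arrays allow no regrouping of samples, and no test for an outlying array was made.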

Results

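Liver RNA of rats was compared on 12 oligonucleotide arrays read in 2 colours, in 6 direct comparisons with 2 dye-swapped arrays each. The RNAs came from intact males, intact females, hypophysectomised males and hypophysectomised females (12-week-old Fischer 344 rats, pools of 3 to 4 livers), and from hypophysectomised males given growth hormone (GH) once (1 pool of 4 livers, taken 30, 60 or 90 min after the injection) or 2 times (1 pool of 5 livers, injections 3 or 4 h apart). Hypophysectomy removes the pituitary and with it GH, which male rats secrete in pulses and female rats almost continuously. Each value is the log2 ratio of the first RNA named to the second, ± SE from limma, from n = 2 arrays, which per the labels hold different pools except for the GH pools. Between 58.4% and 71.1% of the probes were well above background per dye and array, and the number of arrays limits the precision. The X-inactivation transcript Xist, matched by the description of its probe, had a log2 ratio of -6.37 ± 0.20 between intact males and females and -6.11 ± 0.20 between hypophysectomised males and females, and was not called in the other 4 comparisons.

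**Figure D1:**
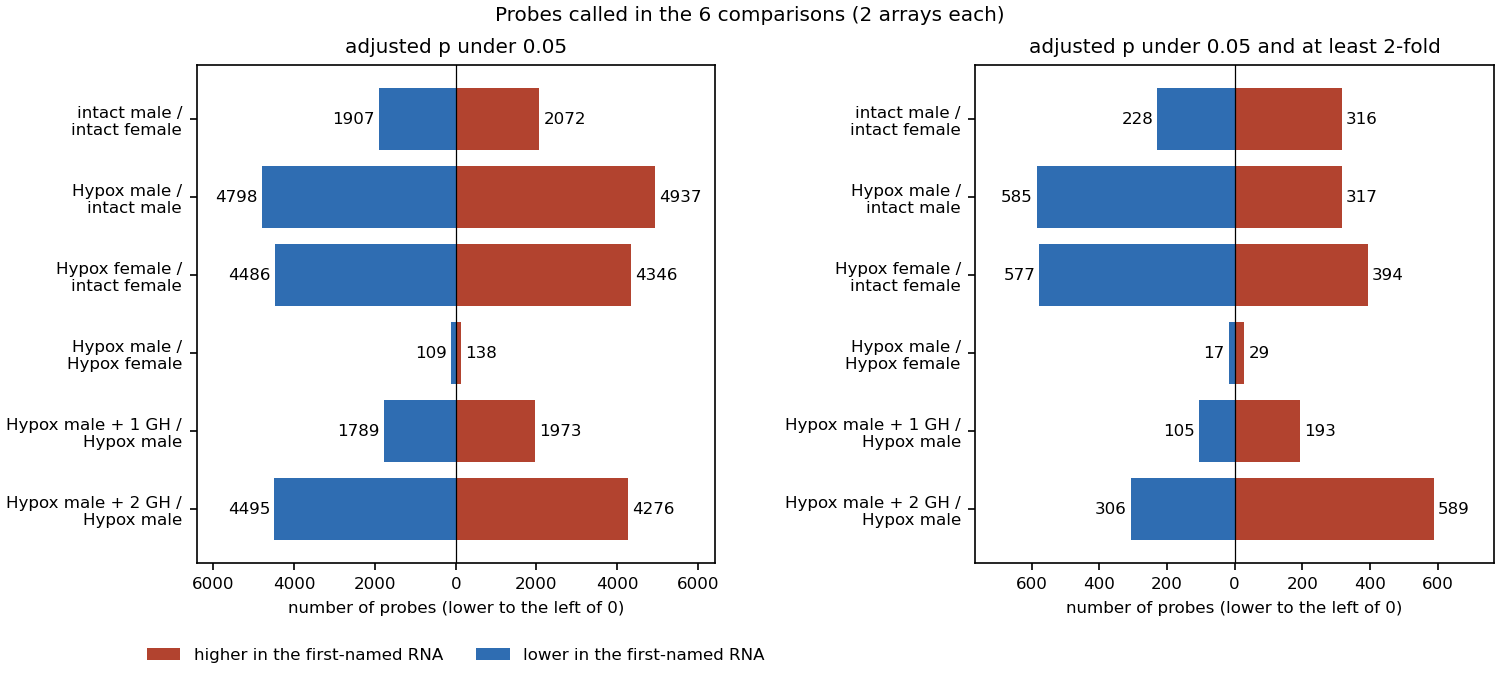
Number of probes called higher or lower (adjusted p at the 0.05 threshold, limma, n = 2 arrays) in each of the 6 comparisons, with those at least 2-fold different marked. Hypophysectomised males and females differed at 247 probes, against 3979 between intact males and females. At an unadjusted p under 0.05 (limma) these counts were 3558 and 7246.

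The comparison of intact males with intact females asks which liver transcripts differ between the sexes. Higher in males were the steroid-hydroxylating cytochromes P450 Cyp3a2 (7.59 ± 0.20, adjusted p = 8.42e-07), Cyp2a2 (4.58 ± 0.12) and Cyp2c13 (4.48 ± 0.17) and the adhesion protein Cdh17 (6.98 ± 0.14). They were joined by the steroid enzymes Hsd3b5 (5.51 ± 0.20) and Dhrs7l1 (4.70 ± 0.30), and the estrogen sulfotransferase Sult1e1 (5.29 ± 0.32). The urinary lipocalins Obp3, Mup5 and Mup4 were higher in males by log2 ratios of 6.39 ± 0.61, 5.09 ± 0.24 and 4.78 ± 0.49. Higher in females were the steroid sulfate hydroxylase Cyp2c12 (-5.43 ± 0.40), the aldo-keto reductases Akr1b7 (-5.82 ± 0.40) and Akr1b8 (-3.57 ± 0.23), and the hydroxysteroid sulfotransferases Sult2a6 (-5.05 ± 0.23) and Sult2a1 (-4.51 ± 0.36). Females were also higher in the plasma glycoprotein A1bg (-4.29 ± 0.33), the desaturase Scd2 (-4.03 ± 0.26), the interferon-inducible GTPase Ifi47 (-3.43 ± 0.06), the prolactin receptor Prlr (-3.42 ± 0.19) and the pancreatic carboxypeptidase Cpa1 (-3.93 ± 0.80), whose adjusted p of 0.013 was the highest of these 20 genes.

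In the list of male-biased liver genes fixed beforehand, 23 of 24 tested members were higher in males and 0 lower (23 up and 0 down adjusted over the list alone, camera adjusted p = 1.62e-24, adjusted p = 0.225 with an estimated correlation). The female-biased list had 14 of 19 members higher in females and 2 higher in males (2 up and 14 down adjusted over the list alone, camera adjusted p = 4.37e-10, adjusted p = 0.389 with an estimated correlation). Its transcription factor Cux2 had a log2 ratio of -4.82 ± 0.13. Cell cycle genes were higher in males for 15 of 26 members and lower for 0 (17 up and 0 down adjusted over the list alone, camera adjusted p = 5.98e-10, adjusted p = 0.225 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, had 1.71 ± 0.16 and the mitotic kinase Cdk1 1.16 ± 0.11. Cholesterol synthesis genes were lower in males for 8 of 23 and higher for 0 (0 up and 12 down adjusted over the list alone, camera adjusted p = 8.90e-05, adjusted p = 0.575 with an estimated correlation), led by the sterol reductase Tm7sf2 (-1.38 ± 0.15). Of 18 fatty acid synthesis genes 5 were lower and 0 higher (0 up and 7 down adjusted over the list alone, camera adjusted p = 0.034, adjusted p = 0.747 with an estimated correlation). Interferon responsive genes were lower in males for 12 of 23 and higher for 1 (1 up and 15 down adjusted over the list alone, camera adjusted p = 1.02e-05, adjusted p = 0.462 with an estimated correlation). Beside them, 7 of 11 macrophage markers were lower and 1 higher (1 up and 10 down adjusted over the list alone, camera adjusted p = 0.00122, adjusted p = 0.529 with an estimated correlation). Lymphocyte markers were lower for 5 of 14 and higher for 0 (0 up and 11 down adjusted over the list alone, camera adjusted p = 0.00118, adjusted p = 0.529 with an estimated correlation). Glucocorticoid responsive genes were higher in males for 5 of 14 and lower for 1 (5 up and 1 down adjusted over the list alone, camera adjusted p = 0.0402, adjusted p = 0.764 with an estimated correlation). They include the gluconeogenic enzyme Pck1 (1.67 ± 0.25). Of 10 markers of pancreas and fat, 2 were higher and 2 lower, Cpa1 with them (2 up and 2 down adjusted over the list alone, camera adjusted p = 0.968).

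In all, 3979 of 25707 probes tested differed between intact males and females, 2072 higher in males and 1907 higher in females, of which 316 and 228 differed at least 2-fold. Leaving out the first or the second array gave 1295 or 1446 probes, and median centring in place of loess gave 261. The Cyp2c, Sult2a, Mup and Serpina3 families hold close relatives that 1 probe may read together. A second probe of Cdh17 had 3.99 ± 0.09 where the brightest had 6.98 ± 0.14, so its size depends on the probe.

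**Figure D2:**
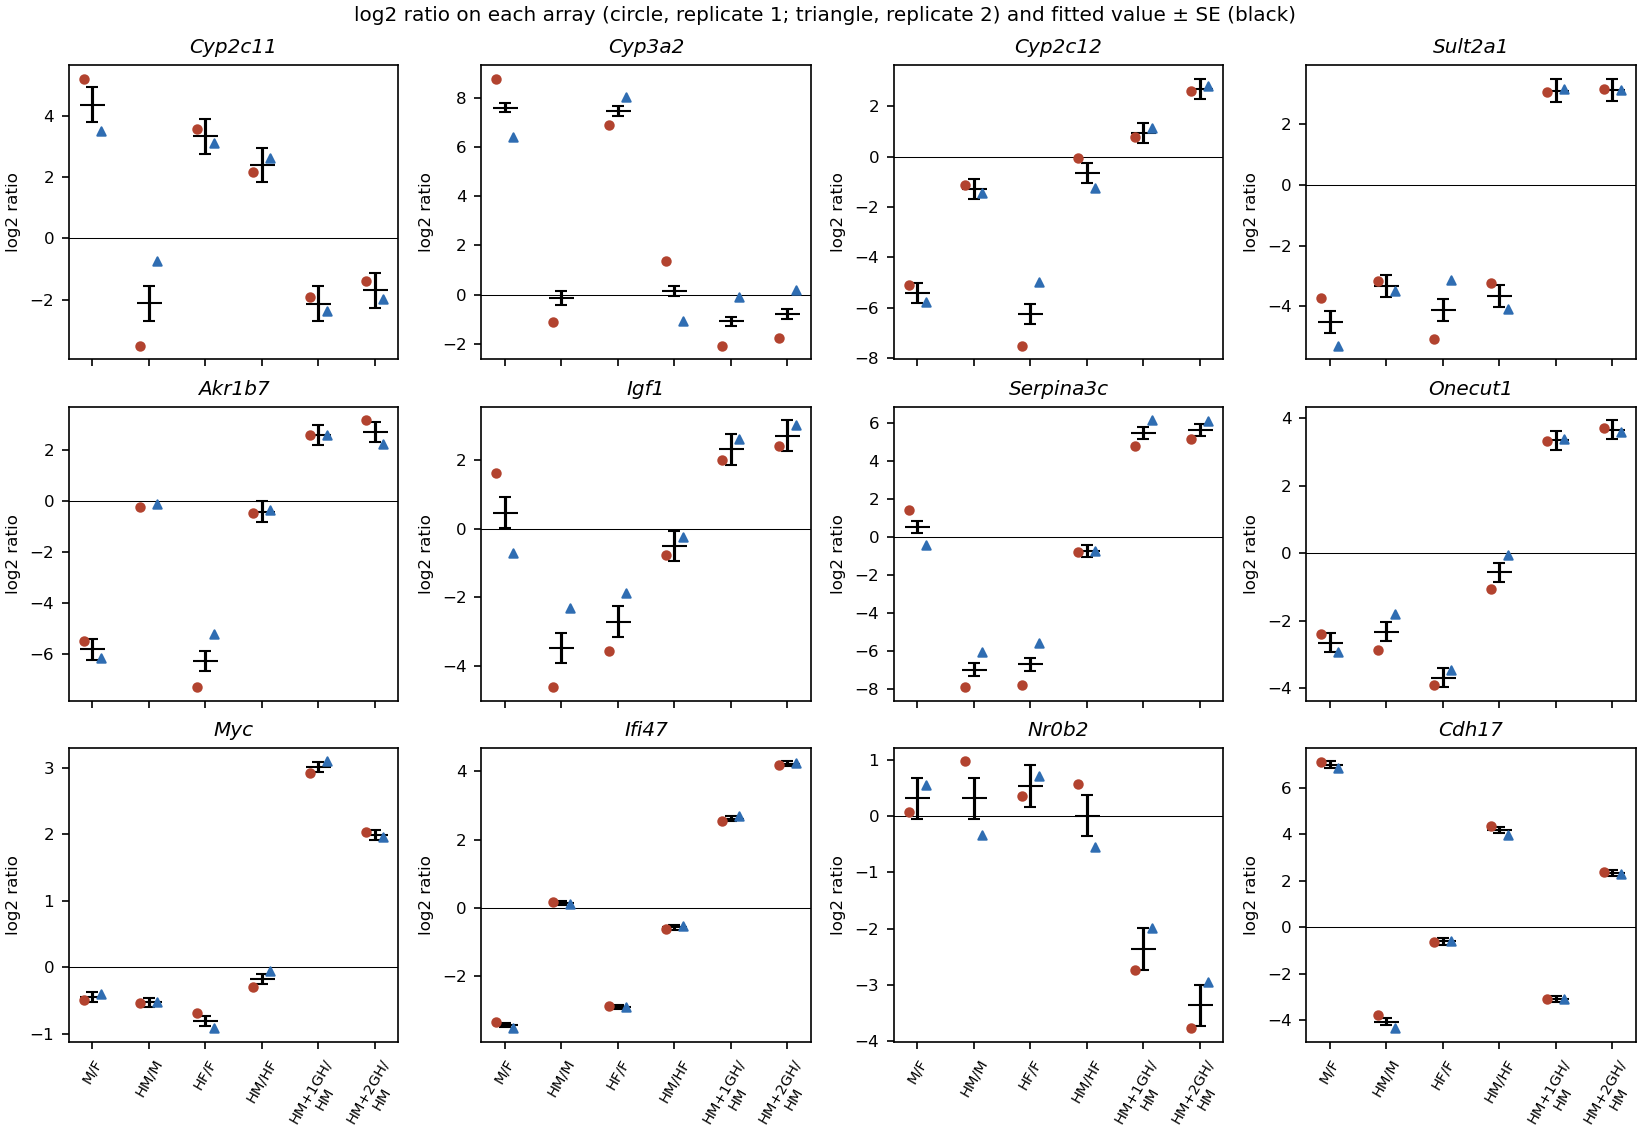
Log2 ratios of 12 genes on each of the 2 arrays (points) of the 6 comparisons, with the fitted value and its SE (bars). Serpina3c fell by 6.99 with hypophysectomy in males and rose by 5.45 and 5.62 after 1 and 2 GH injections.

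Hypophysectomised males were set against intact males to show what the male liver gains and loses without the pituitary. The serine protease inhibitor Serpina3c fell by 6.99 ± 0.32 on the log2 scale (adjusted p = 4.58e-06), the related Spin2a had -5.23 ± 0.49, the lipocalins Obp3, Mup5 and Mup4 had -6.32 ± 0.61, -4.75 ± 0.24 and -4.68 ± 0.49, and Cdh17 had -4.05 ± 0.14. Igf1, the growth factor through which GH acts on many tissues, fell with a log2 ratio of -3.48 ± 0.44, the retinoid-hydroxylating Cyp2c7 with -3.89 ± 0.90 (adjusted p = 0.0136, the highest of the 20), Cdk1 with -3.35 ± 0.11 and the beta globin Hbb with -3.69 ± 0.24. The retinal dehydrogenases Aldh1a4 (4.10 ± 0.18) and Aldh1a1 (2.95 ± 0.17), the IGF-binding protein Igfbp1 (3.00 ± 0.20), the thyroxine carrier Serpina7 (2.99 ± 0.35) and Sult2a6 (2.89 ± 0.23) rose. So did the activin antagonist Fst (2.82 ± 0.45), the clock-controlled transcription factor Dbp (2.82 ± 0.15), the phospholipase Pla1a (2.77 ± 0.18), the transcriptional inhibitor Id1 (2.69 ± 0.17) and metallothionein Mt1 (2.56 ± 0.31).

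Among cell cycle genes in males, 19 of 26 fell and 1 rose (1 up and 21 down adjusted over the list alone, camera adjusted p = 6.16e-12, adjusted p = 0.225 with an estimated correlation). Rrm2 had -3.31 ± 0.16, and the cyclins Ccnb1 and Ccna2 had -2.79 ± 0.08 and -2.74 ± 0.11. STAT5-linked GH targets fell for 11 of 19 and rose for 2 (3 up and 11 down adjusted over the list alone, camera adjusted p = 0.00629, adjusted p = 0.529 with an estimated correlation). Gadd45g, a growth arrest gene, had -2.51 ± 0.26, and Igfals, which carries IGF in plasma, -2.41 ± 0.24. Male-biased genes fell for 13 of 24 and rose for 2 (4 up and 13 down adjusted over the list alone, camera adjusted p = 0.00196, adjusted p = 0.557 with an estimated correlation). The female-biased list, with 9 of 18 higher and 5 lower, did not pass the list test (9 up and 6 down adjusted over the list alone, camera adjusted p = 0.116). Fatty acid synthesis genes fell for 9 of 18 and rose for 1 (1 up and 9 down adjusted over the list alone, camera adjusted p = 0.00266, adjusted p = 0.586 with an estimated correlation), with malic enzyme Me1 at -2.63 ± 0.12. Cholesterol synthesis genes fell for 12 of 23 and rose for 2 (3 up and 13 down adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.747 with an estimated correlation). Thyroid hormone responsive genes fell for 5 of 10 and rose for 2 (2 up and 6 down adjusted over the list alone, camera adjusted p = 0.0402, adjusted p = 0.449 with an estimated correlation). Me1 and the deiodinase Dio1 (-2.42 ± 0.08) led them. Beside these lists, bile duct markers rose for 6 of 9 and fell for 0 (7 up and 0 down adjusted over the list alone, camera adjusted p = 0.00824, adjusted p = 0.529 with an estimated correlation). Endothelial markers rose for 6 of 10 and fell for 1 (6 up and 1 down adjusted over the list alone, camera adjusted p = 0.0404, adjusted p = 0.529 with an estimated correlation). Lymphocyte markers rose for 7 of 14 and fell for 1 (9 up and 1 down adjusted over the list alone, camera adjusted p = 0.039, adjusted p = 0.685 with an estimated correlation).

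Several lists in males went both ways or did not pass the list test. In the IGF and GH receptor axis 4 of 13 rose and 4 fell (5 up and 4 down adjusted over the list alone, camera adjusted p = 0.742). Igfbp1 and Igfbp2 (2.43 ± 0.27) had the largest rises, and Igf1 and Igfals were among those that fell. Bile acid genes fell for 10 of 17 and rose for 2 (4 up and 10 down adjusted over the list alone, camera adjusted p = 0.155). The canalicular exporter Abcc2 had -2.44 ± 0.07. Liver transcription factors rose for 8 of 27, Dbp with them, and fell for 5 (8 up and 5 down adjusted over the list alone, camera adjusted p = 0.561). Those that fell include Onecut1 (-2.32 ± 0.28) and the GH signal transducer Stat5a (-1.20 ± 0.14). Hepatocyte secretory genes fell for 4 of 14, including the apolipoprotein Apoa1 (-2.74 ± 0.40), and rose for 1 (1 up and 4 down adjusted over the list alone, camera adjusted p = 0.265). Erythroid markers fell for 3 of 5 and rose for 2 (2 up and 3 down adjusted over the list alone, camera adjusted p = 0.372). Hbb and the heme synthesis enzyme Alas2 (-2.07 ± 0.08) were among those that fell.

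Of 25977 probes tested in males, 9735 changed with hypophysectomy, 4937 up and 4798 down, of which 317 and 585 changed at least 2-fold. The count was 5647 without the first array, 8954 without the second, 2685 from the 2 arrays fitted alone and 345 (121 up, 224 down) with median centring. In 21 genes, different probes were called in opposite directions. The second probe of Cdh17 had -3.11 ± 0.09.

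In females, hypophysectomy raised part of the genes that were higher in intact males. Of 1947 male-higher probes tested in both comparisons, 780 were called higher and 390 lower. Cyp3a2 rose by 7.44 ± 0.20 on the log2 scale (adjusted p = 1.13e-06), Hsd3b5 by 4.98 ± 0.20, Sult1e1 by 4.73 ± 0.32, and the cytochromes P450 Cyp2a2, Cyp3a18 and Cyp2c13 by 4.32 ± 0.12, 4.28 ± 0.13 and 4.27 ± 0.17. Also higher were the protease inhibitor Spink1l (4.23 ± 0.14), the transporter Ust5r (3.84 ± 0.10), the cortisone reductase Hsd11b1 (3.79 ± 0.09) and the retinol dehydrogenase Rdh16 (3.43 ± 0.11). Serpina3c and Spin2a fell, with log2 ratios of -6.72 ± 0.32 and -5.16 ± 0.49, as did the female-higher Akr1b7 (-6.27 ± 0.40), Cyp2c12 (-6.23 ± 0.40), A1bg (-4.60 ± 0.33), Sult2a1 (-4.10 ± 0.36) and Akr1b8 (-3.66 ± 0.23). The fatty acid elongase Elovl6 (-4.49 ± 0.97, adjusted p = 0.00851, the highest of the 20), Cpa1 (-4.15 ± 0.80) and the transcription factor Onecut1 (-3.70 ± 0.28) fell too.

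Lipid synthesis lists fell in females. Fatty acid synthesis genes fell for 13 of 18 and rose for 0 (0 up and 15 down adjusted over the list alone, camera adjusted p = 2.65e-06, adjusted p = 0.529 with an estimated correlation). The citrate-cleaving enzyme Acly had -2.22 ± 0.65. Cholesterol synthesis genes fell for 18 of 23 and rose for 2 (2 up and 19 down adjusted over the list alone, camera adjusted p = 2.00e-06, adjusted p = 0.536 with an estimated correlation). Insig1, the partner of the sterol sensor, had -2.29 ± 0.33. Cell cycle genes fell for 18 of 25 and rose for 1 (1 up and 19 down adjusted over the list alone, camera adjusted p = 2.83e-08, adjusted p = 0.249 with an estimated correlation), with Cdk1 at -2.09 ± 0.11. Female-biased genes fell for 12 of 19 and rose for 4 (4 up and 13 down adjusted over the list alone, camera adjusted p = 0.00824, adjusted p = 0.586 with an estimated correlation). STAT5-linked targets fell for 9 of 19 and rose for 3 (3 up and 9 down adjusted over the list alone, camera adjusted p = 0.0234, adjusted p = 0.547 with an estimated correlation). The repressor Bcl6 was among those that rose (3.20 ± 0.24). Male-biased genes went both ways, 14 of 24 up and 10 down, and did not pass the list test (14 up and 10 down adjusted over the list alone, camera adjusted p = 0.0704).

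Acute phase proteins rose in females for 12 of 18 and fell for 1 (13 up and 1 down adjusted over the list alone, camera adjusted p = 0.0194, adjusted p = 0.449 with an estimated correlation). The protease trap A2m had 1.93 ± 0.22 and the iron hormone Hamp 1.70 ± 0.26. The median of the acute phase list was 0.08 on the first array and 1.15 on the second, with the dye effect still in both. Hypophysectomised female RNA carried Alexa 555 on the first array and Alexa 647 on the second. Interferon responsive genes fell for 8 of 23 and rose for 4 (4 up and 12 down adjusted over the list alone, camera adjusted p = 0.0402, adjusted p = 0.709 with an estimated correlation). Ifi47 had a log2 ratio of -2.90 ± 0.06. Beside them, endothelial markers rose for 5 of 9 and fell for 0 (7 up and 0 down adjusted over the list alone, camera adjusted p = 0.0272, adjusted p = 0.536 with an estimated correlation). Lymphocyte markers rose for 4 of 14 and fell for 1 (4 up and 1 down adjusted over the list alone, camera adjusted p = 0.0433, adjusted p = 0.709 with an estimated correlation). Pancreas and fat markers, with Cpa1 in the list, fell for 2 of 10 and rose for 1 (1 up and 1 down adjusted over the list alone, camera adjusted p = 0.974).

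Of 24318 probes tested in females, 8832 changed, 4346 up and 4486 down, of which 394 and 577 changed at least 2-fold. The count was 3581 without the first array, 4160 without the second and 371 (143 up, 228 down) with median centring. Both sexes changed the same way at 5974 probes, against 1713.5 expected if calls were independent, and opposite ways at 215 (r = 0.72 across probes, no RNA shared, probes not being independent replicates). In 15 genes, different probes were called in opposite directions.

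The difference between the 2 responses was tested as the change in males minus the change in females. It was negative for male-higher genes that rose in females, Cyp3a2 (-7.51 ± 0.22, with 1 array value for hypophysectomy in males), Hsd3b5 (-4.60 ± 0.20), Cyp2c13 (-3.89 ± 0.17), Cyp2a2 (-3.88 ± 0.12) and the peroxisomal oxidase Hao2 (-3.88 ± 0.09), and for Obp3 (-4.08 ± 0.61), which fell further in males. It was positive for the female-higher genes Cyp2c12 (4.85 ± 0.40), Sult2a6 (3.98 ± 0.23) and Scd2 (3.97 ± 0.26), which fell in females. The same direction was called for Akr1b7, Cpa1 and A1bg, but the sizes of these 3 are not exact. Neither RNA was well above background with hypophysectomy in males for Akr1b7 and Cpa1, nor between the hypophysectomised sexes for Cpa1 and A1bg.

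The response of male-biased genes was lower in males than in females for 23 of 24 members and higher for 0 (0 up and 23 down adjusted over the list alone, camera adjusted p = 2.57e-21, adjusted p = 0.225 with an estimated correlation). For female-biased genes it was higher in males for 13 of 19 and lower for 2 (13 up and 2 down adjusted over the list alone, camera adjusted p = 1.67e-08, adjusted p = 0.449 with an estimated correlation). Cell cycle genes had a lower response in males for 16 of 26 and a higher one for 0 (0 up and 20 down adjusted over the list alone, camera adjusted p = 1.49e-10, adjusted p = 0.225 with an estimated correlation). Higher responses in males were called for 10 of 23 cholesterol synthesis genes and lower ones for 0 (16 up and 0 down adjusted over the list alone, camera adjusted p = 4.54e-07, adjusted p = 0.529 with an estimated correlation). Of 18 fatty acid synthesis genes 4 had a higher and 1 a lower response in males (6 up and 1 down adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.739 with an estimated correlation). Interferon responsive genes had 5 higher and 1 lower of 23 (9 up and 2 down adjusted over the list alone, camera adjusted p = 0.00286, adjusted p = 0.542 with an estimated correlation). Hepatocyte secretory genes had 0 higher and 2 lower of 14 (0 up and 3 down adjusted over the list alone, camera adjusted p = 0.0256, adjusted p = 0.731 with an estimated correlation). Bile duct markers had 1 higher and 0 lower of 9 (3 up and 0 down adjusted over the list alone, camera adjusted p = 0.0433, adjusted p = 0.563 with an estimated correlation).

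The responses differed between the sexes at 3333 of 27061 probes, 1570 more positive in males and 1763 more negative. Leaving out an array of the sex comparison of intact rats gave 1888 or 2167, leaving out the first array of hypophysectomy in females gave 2041, median centring gave 157, and each of the 2 estimates of the difference, which come from separate arrays with RNA of the same 4 kinds, gave 1212 and 1300, with 1046 in both. These estimates were also set against each other, and limma called 0 probes different, with 168 at an unadjusted p under 0.05 against 1353 expected, fewer than independent arrays would give. The fit takes the arrays as independent, but the 2 estimates share kinds of RNA and are not independent replicates of the difference.

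Without the pituitary, male and female livers still differed in some sex-biased genes. Cdh17 (4.17 ± 0.14, adjusted p = 7.39e-06), Dhrs7l1 (3.02 ± 0.30), Sult1e1 (2.76 ± 0.32), Hsd3b5 (1.75 ± 0.20), Mup5 (1.67 ± 0.24), the steroid enzyme Hsd3b2 (1.49 ± 0.19) and the fatty acid hydroxylase Cyp4a8 (1.41 ± 0.12) were higher in males. So were the phosphatase Ctdsp1 (2.65 ± 0.09), the calcium-binding protein Cib2 (1.93 ± 0.29) and the ciliary dynein Dnah9 (1.59 ± 0.14). Higher in females were Sult2a1 (-3.65 ± 0.36), Hbb (-2.30 ± 0.24), the leptin receptor Lepr (-1.31 ± 0.16), Sult2a6 (-1.31 ± 0.23, adjusted p = 0.0449, the highest of the 20), Prlr (-1.28 ± 0.19) and Alas2 (-0.9996 ± 0.076). The dicarboxylate transporter Slc13a3 (-0.97 ± 0.08), the plasma protein Fetub (-0.76 ± 0.12), the fatty acid transporter Cd36 (-0.72 ± 0.12) and the procollagen protease enhancer Pcolce (-0.70 ± 0.10) were higher in females as well. The second probe of Cdh17 had 1.95 ± 0.09.

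Male-biased genes were higher in hypophysectomised males for 5 of 24 members and lower for 0 (14 up and 0 down adjusted over the list alone, camera adjusted p = 1.25e-15, adjusted p = 0.249 with an estimated correlation). Female-biased genes were lower for 6 of 18 and higher for 0 (0 up and 9 down adjusted over the list alone, camera adjusted p = 5.98e-10, adjusted p = 0.338 with an estimated correlation). Interferon responsive genes were lower for 1 of 23, Ifi47 (-0.57 ± 0.06), and higher for 0 (0 up and 2 down adjusted over the list alone, camera adjusted p = 0.00409, adjusted p = 0.547 with an estimated correlation). Beside them, macrophage markers were lower for 3 of 11 and higher for 0 (1 up and 8 down adjusted over the list alone, camera adjusted p = 0.000208, adjusted p = 0.483 with an estimated correlation). Lymphocyte markers were lower for 1 of 14 and higher for 0 (0 up and 1 down adjusted over the list alone, camera adjusted p = 0.00118, adjusted p = 0.529 with an estimated correlation). Endothelial markers were lower for 0 of 10 and higher for 0, with 3 at an unadjusted p under 0.05 (0 up and 1 down adjusted over the list alone, camera adjusted p = 0.00764, adjusted p = 0.449 with an estimated correlation). Of 25 cell cycle genes limma called 0 in either direction, with 6 at an unadjusted p under 0.05 and a median of -0.12 (0 up and 0 down adjusted over the list alone, camera adjusted p = 0.0468, adjusted p = 0.582 with an estimated correlation). The acute phase, bile duct and pancreas and fat lists also passed the list test, with adjusted p = 0.039, 0.0428 and 0.0404 (adjusted p = 0.483, 0.563 and 0.739 with an estimated correlation). Of their 18, 9 and 9 members limma called 0, with 6, 2 and 1 at an unadjusted p under 0.05. Adjusted over the list alone, limma called 0 up and 3 down of the acute phase members and 0 of the bile duct and pancreas and fat members. Their medians on the 2 arrays, with the dye effect still in them, had opposite signs (0.38 and -0.80, 0.17 and -0.01, -0.08 and 0.90).

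Of 26031 probes tested, 247 differed, 138 higher in males and 109 higher in females, with 29 and 17 at least 2-fold. At an unadjusted p under 0.05 limma had 3558 probes here (1302 expected) and 7246 between the intact sexes (1285 expected). With fewer small p-values the adjusted threshold is stricter, so part of the drop in calls from the intact sexes comes from it. Across probes the 2 arrays of this comparison had r = 0.045, against 0.57 to 0.83 in the other 5 comparisons. These ratios still held the dye effect, which enters dye-swapped arrays with opposite sign and which the fit removes. It lowers r most where the differences are small, so this r is no direct measure of how well the fitted values repeat. With 1 coefficient per RNA group limma called 1007 probes (491 higher in males, 516 lower). Without background correction limma called 393 (165 higher, 228 lower), so the balance of directions also depends on the setting. The count was 22 without the first array, 46 without the second, 6 from the 2 arrays fitted alone, 7 with median centring, 143 with replicate blocks and 453 with slide blocks.

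Most sex-biased transcripts changed with hypophysectomy in at least 1 sex, 3340 of 3979 (83.9%). Of all probes tested, 37.5% were called in males and 36.3% in females, so part of this share is the general rate. The count of 3340 was lower with median centring and without the dye coefficient, with values in the part on processing. By calls, without a test of the difference for each class, the 316 male-higher probes of at least 2-fold held 81 called lower in males and not in females, 76 called higher in females and not in males, 55 with both calls, 51 lower in both sexes, 31 higher in both, 1 called higher in males and not in females, and 21 called in neither. The 228 female-higher ones held 73 called lower in females and not in males, 51 lower in both, 49 higher in males and lower in females, 25 called higher in males and not in females, 24 higher in both, 2 called higher in females and not in males, and 4 called in neither. Untested probes count as not called here, 23 of the 316 in females and 20 of the 228 in males. After hypophysectomy 65 of the male-higher and 29 of the female-higher probes were still called in the same direction. Over the 300 male-higher and 209 female-higher probes tested in both, the median difference in the intact direction went from 1.56 to 0.40 and from 1.49 to 0.26. Cyp3a2, Cyp2c12 and Akr1b7 were not among those still called, while Cdh17, Sult2a1 and Xist were. A lost call is not a lost difference, because the adjusted threshold was stricter between the hypophysectomised sexes. The comparison of intact sexes shares RNA with both hypophysectomy comparisons. With hypophysectomy in males, calls were opposite at 1890 probes against 741.7 expected, and the covariance across probes was -0.0641 against -0.0059 in simulations of unchanged groups (r = -0.34, simulated -0.50). With hypophysectomy in females, the covariance was 0.0708 against 0.0062 (r = 0.35, simulated 0.50). Both correlations are weaker than the simulated ones, which lie near 0.50 in size by construction. There each array's variance was split equally over its 2 RNAs, so these correlations cannot decide how much comes from shared RNA. Both covariances were further from 0 than simulated, and part of the excess of calls may come from the shared RNA. The 2 sex comparisons, which share none, had r = 0.51 across probes, which are not independent replicates.

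**Figure D3:**
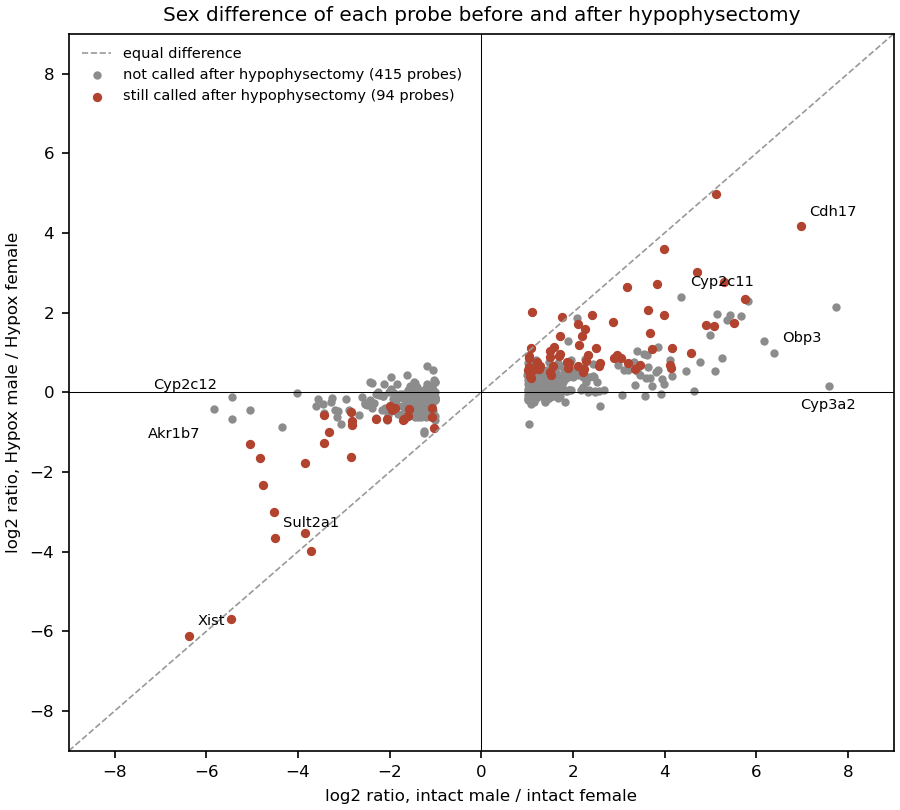
Log2 ratio of males to females before (horizontal) and after (vertical) hypophysectomy, for 509 probes at least 2-fold sex-biased in intact rats and tested in both. Points still called after hypophysectomy (94) and no longer called (415) are coloured apart, and the dashed line marks equal differences. A point no longer called can still differ between the sexes.

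A single GH injection raised Serpina3c (5.45 ± 0.32, adjusted p = 7.82e-05), Spin2a (4.40 ± 0.49), Mup4 (3.82 ± 0.49), Mup5 (3.45 ± 0.24) and Obp3 (3.318 ± 0.610) in hypophysectomised males, a comparison that asks which genes respond early to GH. Regulatory genes rose as well, namely Onecut1 (3.35 ± 0.28), Gadd45g (3.03 ± 0.26), the growth-linked transcription factor Myc (3.01 ± 0.07) and the calcineurin regulator Rcan1 (2.68 ± 0.48), as did Sult2a1 (3.103 ± 0.362). The male-higher genes Dhrs7l1 (-3.80 ± 0.30), Cdh17 (-3.08 ± 0.14), Sult1e1 (-2.50 ± 0.32) and Cyp2c11, the main male testosterone hydroxylase (-2.14 ± 0.57, adjusted p = 0.0428, the highest of the 20), fell. Also lower were Rdh16 (-2.60 ± 0.11), the bile acid-induced repressor Nr0b2 (-2.36 ± 0.37), the amino acid transporter Slc3a1 (-1.90 ± 0.19), Tsx (-1.89 ± 0.34), the aldo-keto reductase Akr1c3 (-1.83 ± 0.10) and the neuronal growth protein Gap43 (-1.81 ± 0.34).

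STAT5-linked targets rose for 10 of 19 and fell for 1 (11 up and 1 down adjusted over the list alone, camera adjusted p = 4.99e-05, adjusted p = 0.449 with an estimated correlation), with Igf1 at 2.31 ± 0.44. Female-biased genes rose for 8 of 19 and fell for 1 (9 up and 3 down adjusted over the list alone, camera adjusted p = 0.00102, adjusted p = 0.536 with an estimated correlation). Cux2 had 3.74 ± 0.13, and Akr1b7 was at least 5.73-fold higher. Male-biased genes went both ways, 9 of 24 up and 12 down, and did not pass the list test (10 up and 13 down adjusted over the list alone, camera adjusted p = 0.726). Immediate early genes, switched on within minutes of a stimulus, rose for 7 of 27 and fell for 2 (10 up and 2 down adjusted over the list alone, camera adjusted p = 0.0468, adjusted p = 0.747 with an estimated correlation). Egr1 (1.91 ± 0.36) and Jun (1.35 ± 0.33) were among them. Cell cycle genes rose for 8 of 25 and fell for 2 (9 up and 3 down adjusted over the list alone, camera adjusted p = 0.0103, adjusted p = 0.529 with an estimated correlation). Thyroid hormone responsive genes rose for 5 of 10 and fell for 1 (7 up and 2 down adjusted over the list alone, camera adjusted p = 0.0381, adjusted p = 0.449 with an estimated correlation). Drug-metabolising genes fell for 12 of 27 and rose for 2 (4 up and 13 down adjusted over the list alone, camera adjusted p = 0.00881, adjusted p = 0.536 with an estimated correlation).

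Metabolic, interferon and acute phase lists also held members called after 1 injection. Glucocorticoid responsive genes fell for 4 of 15 and rose for 0 (0 up and 4 down adjusted over the list alone, camera adjusted p = 0.0468, adjusted p = 0.764 with an estimated correlation). Fatty acid oxidation genes fell for 5 of 23 and rose for 0 (0 up and 6 down adjusted over the list alone, camera adjusted p = 0.0402, adjusted p = 0.747 with an estimated correlation). Cholesterol synthesis genes fell for 4 of 23 and rose for 2 (2 up and 9 down adjusted over the list alone, camera adjusted p = 0.0235, adjusted p = 0.764 with an estimated correlation). Interferon responsive genes rose for 9 of 23 and fell for 0 (10 up and 0 down adjusted over the list alone, camera adjusted p = 3.89e-06, adjusted p = 0.449 with an estimated correlation). Ifi47 rose by 2.62 ± 0.06. Acute phase proteins rose for 8 of 18 and fell for 0 (9 up and 0 down adjusted over the list alone, camera adjusted p = 0.0482, adjusted p = 0.529 with an estimated correlation). Their median was -0.20 on the first array and 1.03 on the second, with the dye effect still in both. The 1-injection RNA carried Alexa 555 on the first array and Alexa 647 on the second.

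Markers of other cell types moved beside these lists after 1 injection. Macrophage markers rose for 6 of 11 and fell for 1 (9 up and 2 down adjusted over the list alone, camera adjusted p = 0.00824, adjusted p = 0.542 with an estimated correlation). Lymphocyte markers rose for 2 of 14 and fell for 0 (2 up and 0 down adjusted over the list alone, camera adjusted p = 0.0381, adjusted p = 0.685 with an estimated correlation). Endothelial markers rose for 2 of 10 and fell for 0 (3 up and 0 down adjusted over the list alone, camera adjusted p = 0.0468, adjusted p = 0.536 with an estimated correlation). Stellate cell markers passed the list test with 0 of 12 members called by limma, 5 at an unadjusted p under 0.05 and a median of 0.33 (0 up and 0 down adjusted over the list alone, camera adjusted p = 0.0402, adjusted p = 0.764 with an estimated correlation). That median was 0.58 on the first array and 0.07 on the second. Bile duct markers fell for 2 of 10 and rose for 0 (0 up and 3 down adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.529 with an estimated correlation). Skeletal muscle markers, a list added after the data were seen, rose for 16 of 27 and fell for 1, with a median of 0.47.

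Of 26353 probes tested, 3762 changed after 1 injection, 1973 up and 1789 down, of which 193 and 105 changed at least 2-fold. The count was 629 without the first array, 558 without the second and 812 from the 2 arrays fitted alone. With median centring limma called 0, with 997 probes at an unadjusted p under 0.05. Both arrays carried the same GH pool, so the spread between GH-treated pools is not in these p-values, and the 4 GH arrays alone gave 12263, an alternative chosen after seeing the data.

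Following the second GH injection, the rise of Serpina3c (5.62 ± 0.32, adjusted p = 1.31e-05), Spin2a (4.64 ± 0.49), Onecut1 (3.64 ± 0.28), Mup4 (3.58 ± 0.49), Gadd45g (3.55 ± 0.26) and Mup5 (3.45 ± 0.24) was again called against hypophysectomised males. Ifi47 (4.22 ± 0.06), the chemokine Cxcl9 (3.47 ± 0.14), the NAD synthesis enzyme Nampt (3.56 ± 0.18) and the stress-induced transcription factor Atf3 (3.38 ± 0.19) rose as well. The list of falling genes held Nr0b2 at -3.36 ± 0.37, the clock gene Per2 at -2.15 ± 0.21, the glucose-releasing phosphatase G6pc1 at -1.90 ± 0.19 and the xenobiotic receptor Nr1i3 at -1.79 ± 0.10. Aldh1a4 (-2.11 ± 0.18), the leucine zipper protein Tsc22d1 (-1.97 ± 0.46, adjusted p = 0.0122, the highest of the 20), the protease inhibitor Serpina5 (-1.93 ± 0.10), the amino acid transporter Slc16a10 (-1.84 ± 0.26), the olfactory receptor Olr59 (-1.83 ± 0.11) and the kinase Map2k6 (-1.77 ± 0.13) were lower.

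Interferon responsive genes rose for 19 of 23 and fell for 0 (22 up and 0 down adjusted over the list alone, camera adjusted p = 3.38e-15, adjusted p = 0.225 with an estimated correlation). The chemokine Cxcl10 had 3.23 ± 0.10, the antiviral Rsad2 2.97 ± 0.06 and Isg15 2.90 ± 0.07. Beside them, 2 of 14 lymphocyte markers rose and 0 fell (2 up and 0 down adjusted over the list alone, camera adjusted p = 0.486). For macrophage markers limma called 0 of 11, with 1 at an unadjusted p under 0.05 (0 up and 0 down adjusted over the list alone, camera adjusted p = 0.97). STAT5-linked targets rose for 15 of 20 and fell for 2 (15 up and 2 down adjusted over the list alone, camera adjusted p = 6.15e-05, adjusted p = 0.449 with an estimated correlation). The cytokine signalling suppressor Socs2 had 3.28 ± 0.13. Immediate early genes rose for 16 of 28 and fell for 1 (18 up and 1 down adjusted over the list alone, camera adjusted p = 8.68e-06, adjusted p = 0.529 with an estimated correlation). Jun had 2.59 ± 0.33 and Klf6 2.39 ± 0.18. Acute phase proteins rose for 13 of 18 and fell for 0 (14 up and 0 down adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.338 with an estimated correlation). A2m had 2.34 ± 0.22 and the fibrinogen chain Fga 1.80 ± 0.09. Drug-metabolising genes fell for 15 of 27 and rose for 1 (1 up and 17 down adjusted over the list alone, camera adjusted p = 2.57e-05, adjusted p = 0.449 with an estimated correlation). Cyp2b2 had -1.46 ± 0.18 and Cyp1a1 -1.38 ± 0.25. Amino acid catabolism and urea cycle genes fell for 11 of 20 and rose for 1 (1 up and 12 down adjusted over the list alone, camera adjusted p = 0.00588, adjusted p = 0.764 with an estimated correlation), with arginase Arg1 at -1.21 ± 0.28.

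Of 28432 probes tested, 8771 changed after 2 injections, 4276 up and 4495 down, of which 589 and 306 changed at least 2-fold. Here too both arrays carried 1 GH pool. The count was 4183 without the first array, 4870 without the second, 3675 from the 2 arrays fitted alone, 75 with median centring and 14860 from the 4 GH arrays alone, an alternative chosen after seeing the data. Different probes of 6 genes were called in opposite directions.

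**Figure D4:**
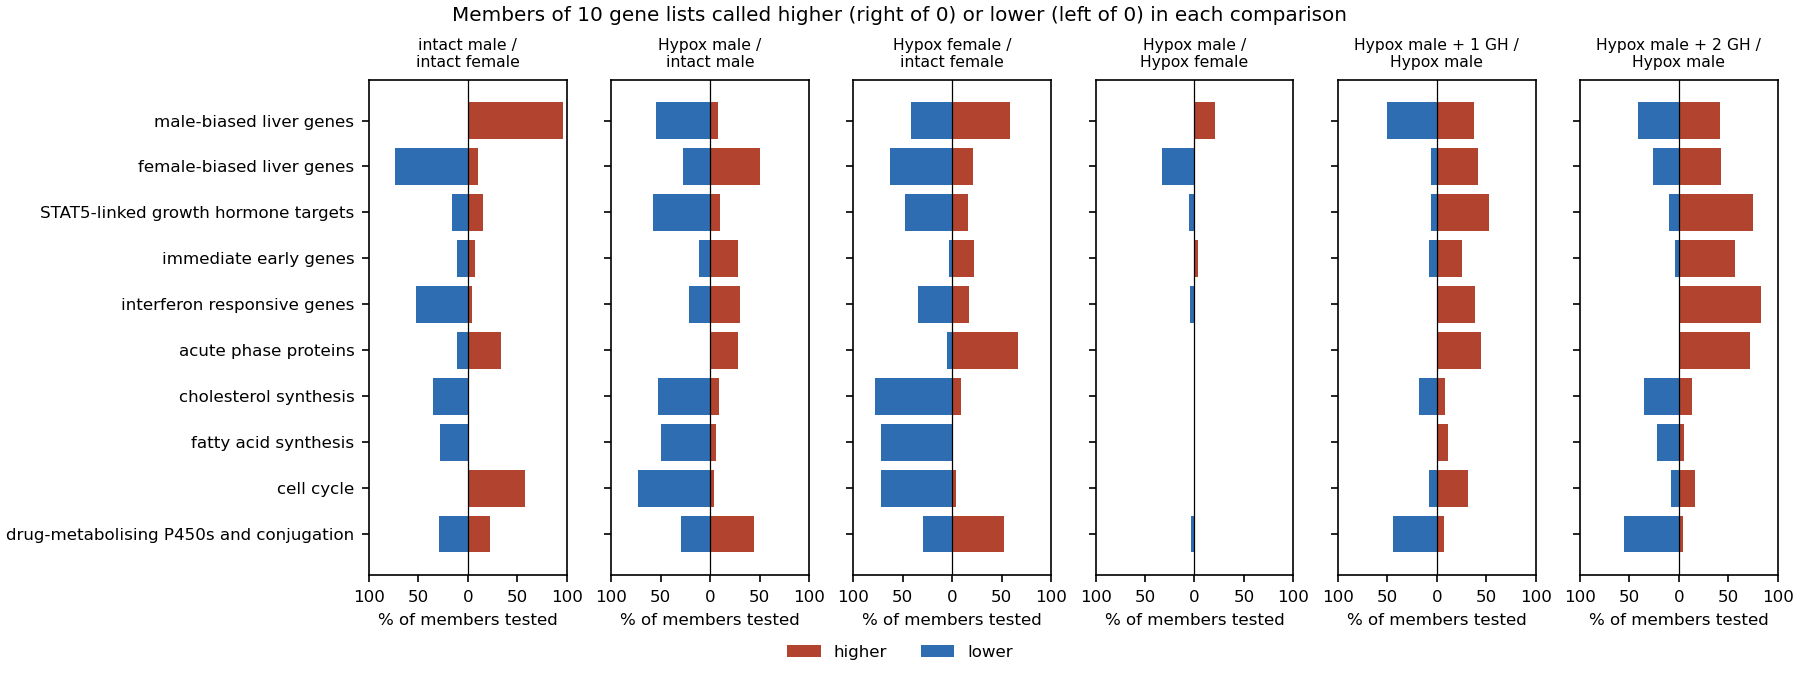
Share of the tested members of 10 gene lists called higher (right of 0) or lower (left of 0) in each comparison, in percent. Cell cycle genes were lower in 19 of 26 and 18 of 25 members after hypophysectomy in males and females, and interferon responsive genes higher in 19 of 23 after 2 GH injections.

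The 2 GH pools were set against each other through the hypophysectomised males on both. Higher after 2 injections than after 1 were Cdh17 (5.41 ± 0.20), the interferon-induced Cxcl9 (3.58 ± 0.20), Cxcl10 (3.17 ± 0.15) and Rsad2 (2.63 ± 0.08), the glutathione transferase Gstm3 (3.03 ± 0.21) and Atf3 (2.69 ± 0.27). Lower were the muscle proteins Myl11 (-1.71 ± 0.08), Myh7 (-1.41 ± 0.09) and Ckm (-1.25 ± 0.08), the junction protein Cldn1 (-1.49 ± 0.12), the alcohol dehydrogenase Adh7 (-1.38 ± 0.22) and the sphingomyelinase Smpd3 (-1.38 ± 0.35, adjusted p = 0.0491, the highest of the 12). The ratios of Myh7 and Ckm are no exact sizes, as neither was well above background on both arrays in the 2-injection pool.

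Interferon responsive genes were higher after 2 injections for 15 of 23 and lower for 0 (18 up and 1 down adjusted over the list alone, camera adjusted p = 1.01e-15, adjusted p = 0.225 with an estimated correlation). Beside them, macrophage markers were higher for 0 of 11 and lower for 2 (1 up and 5 down adjusted over the list alone, camera adjusted p = 0.0157, adjusted p = 0.557 with an estimated correlation). Immediate early genes were higher for 7 of 28 and lower for 1 (9 up and 1 down adjusted over the list alone, camera adjusted p = 0.000301, adjusted p = 0.536 with an estimated correlation). Acute phase proteins were higher for 6 of 18 and lower for 0 (9 up and 0 down adjusted over the list alone, camera adjusted p = 0.0234, adjusted p = 0.449 with an estimated correlation). Drug-metabolising genes were lower for 6 of 27 and higher for 1 (1 up and 11 down adjusted over the list alone, camera adjusted p = 0.00156, adjusted p = 0.529 with an estimated correlation). Bile acid genes were lower for 3 of 17 and higher for 0 (2 up and 6 down adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.557 with an estimated correlation). Cell cycle genes were lower for 4 of 25 and higher for 0 (0 up and 9 down adjusted over the list alone, camera adjusted p = 0.0196, adjusted p = 0.536 with an estimated correlation). Of 18 fatty acid synthesis genes 1 was lower and 0 higher (0 up and 1 down adjusted over the list alone, camera adjusted p = 0.0292, adjusted p = 0.747 with an estimated correlation). Of 20 amino acid catabolism genes 1 was lower and 0 higher (0 up and 1 down adjusted over the list alone, camera adjusted p = 0.0241, adjusted p = 0.825 with an estimated correlation). Stellate cell markers were lower for 2 of 12 and higher for 1 (1 up and 4 down adjusted over the list alone, camera adjusted p = 0.0402, adjusted p = 0.764 with an estimated correlation). The added muscle markers were lower for 13 of 27, with a median of -0.42.

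Of 28583 probes tested, 2580 differed, 1392 higher and 1188 lower after 2 injections. This sets 1 pool against 1 pool, each on 2 arrays, so the p-values hold no spread between GH-treated pools and speak for these 2 pools alone. The count was 534 or 955 without an array of the 2-injection comparison, 461 or 645 without one of the 1-injection comparison, 1153 without the dye coefficient, 4056 without background correction and 10723 from the 4 GH arrays alone. With median centring limma called 0, with 476 probes at an unadjusted p under 0.05. Calls went the same way after 1 and 2 injections at 2644 probes against 622.3 expected and opposite ways at 78, with a covariance across probes of 0.0897 against 0.0059 simulated for the shared hypophysectomised male RNA (r = 0.69 against 0.50), so part of the overlap may come from that RNA.

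Among all sex-biased probes, those higher in males fell and those higher in females rose after GH more often than independent calls would give. Of the 1980 male-higher probes tested in both, 511 fell after 1 injection against 140.1 expected (Fisher's exact test, 2-sided, 8 tests, odds ratio 6.02, adjusted p = 2.88e-166), and of the 1828 female-higher probes 508 rose against 141.7 (odds ratio 5.86, adjusted p = 8.08e-162). Fewer went the other way, 180 male-higher probes rising against 153.5 (odds ratio 1.21, adjusted p = 0.0227) and 102 female-higher ones falling against 129.4 (odds ratio 0.762, adjusted p = 0.0104). After 2 injections 716 male-higher probes fell against 351.9 (odds ratio 2.92, adjusted p = 3.96e-92) and 480 female-higher probes rose against 308.3 (odds ratio 1.85, adjusted p = 1.55e-25), while 380 male-higher ones rose against 331.8 (odds ratio 1.20, adjusted p = 0.0039) and 419 female-higher ones fell against 326.9 (odds ratio 1.40, adjusted p = 2.65e-08). At 2-fold in both comparisons, 51 male-higher probes fell and 23 rose after 1 injection (odds ratios 96.4 and 12.3), but 45 fell and 46 rose after 2 (16.5 and 8.07). Of female-higher ones, 30 rose and 3 fell after 1 (26.6 and 3.63), and 33 rose and 15 fell after 2 (8.28 and 6.58). Dhrs7l1, Cdh17, Sult1e1 and Cyp2c11 were male-higher genes that fell after 1 injection, and Sult2a1 and Cux2 female-higher genes that rose. Of all probes tested, sex-biased or not, 14.3% were called after 1 injection and 30.8% after 2. In all, 2344 of the 3979 sex-biased probes (58.9%) responded to GH, 169 of them at least 2-fold in both. The sex comparison and the GH comparisons share no RNA, but they share 1 variance per probe. That could raise overlaps in both directions, and the expected numbers and Fisher p-values leave it out. Probes are not independent replicates either, and the count was 1288 without the dye coefficient and 9 with median centring.

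Part of the change that followed hypophysectomy in males was called in the opposite direction after GH. Serpina3c, Spin2a, Mup4, Mup5 and Igf1, which fell with hypophysectomy, rose after GH, and Aldh1a4, which rose, fell after 2 injections. Of the 9735 probes changed by hypophysectomy in males, 3832 (39.4%) were called in the opposite direction after 1 or 2 injections. Calls were opposite at 1825 probes after 1 injection against 699.3 expected and at 3441 after 2 against 1624.5. Because hypophysectomised male RNA stands on both sides, the covariances across probes, -0.0654 (r = -0.46) and -0.0732 (r = -0.37), are set beside simulated ones of -0.0060 and -0.0059 (r = -0.50 for each). The correlations are weaker than the simulated ones, which lie near -0.50 by construction. There each array's variance was split equally over its 2 RNAs, so these correlations cannot decide how much comes from shared RNA. Both covariances were further from 0 than simulated, and part of the excess of calls may come from the shared RNA. Hypophysectomy in females, which shares no RNA with the GH arrays and was added after seeing the data, gave 3630 reversed probes, with 1866 opposite after 1 injection against 666.4 expected (r = -0.50) and 3216 after 2 against 1563.9 (r = -0.35). Probes are not independent replicates, and each has 1 variance for all comparisons, which the expected numbers leave out. The count in males was 2518 without the dye coefficient and 20 with median centring.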

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

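The tests of muscle in the hypophysectomised male pools, of immune cells, of normalization as the whole difference, of the single 2-injection pool, of 1 probe or array and of unequal pools were chosen only after the results they measure were seen, as were the patterns weighed here and the muscle and intestinal marker lists. The genes listed in this part are here because the change of one group differed from that of another in a test of the difference itself (limma, n = 2 arrays per comparison, but 1 value for Cyp3a2 with hypophysectomy in males).

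The change with hypophysectomy differed between males and females at 3333 probes. As the change in males minus that in females (log2, ± SE), positive differences were those of the aldo-keto reductase Akr1b7 (5.73 ± 0.40, adjusted p = 6.72e-05), the carboxypeptidase Cpa1 (5.11 ± 0.80, adjusted p = 0.00489), Cyp2c12 (4.85 ± 0.40, adjusted p = 1.67e-04), A1bg (4.01 ± 0.33, adjusted p = 1.67e-04), Sult2a6 (3.98 ± 0.23, adjusted p = 2.27e-05) and Scd2 (3.97 ± 0.26, adjusted p = 5.22e-05). For Akr1b7 and Cpa1 neither RNA was well above background with hypophysectomy in males, nor for Cpa1 and A1bg between the hypophysectomised sexes, so these 3 sizes are not exact. Negative ones were those of Cyp3a2 (-7.51 ± 0.22, adjusted p = 2.25e-06), Hsd3b5 (-4.60 ± 0.20, adjusted p = 5.07e-06), the lipocalin Obp3 (-4.08 ± 0.61, adjusted p = 0.00384), Cyp2c13 (-3.89 ± 0.17, adjusted p = 5.41e-06), Cyp2a2 (-3.88 ± 0.12, adjusted p = 7.97e-07) and Hao2 (-3.88 ± 0.09, adjusted p = 2.63e-07).

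The change after 2 GH injections differed from that after 1 at 2580 probes, with 1 GH pool each, so that the p-values hold no spread between GH-treated pools. It was more positive for the adhesion protein Cdh17 (5.41 ± 0.20, adjusted p = 2.50e-05), Cxcl9 (3.58 ± 0.20, adjusted p = 8.29e-05), Cxcl10 (3.17 ± 0.15, adjusted p = 5.49e-05), Gstm3 (3.03 ± 0.21, adjusted p = 2.50e-04), Atf3 (2.69 ± 0.27, adjusted p = 0.00131) and Rsad2 (2.63 ± 0.08, adjusted p = 2.06e-05). It was more negative for Myl11 (-1.71 ± 0.08, adjusted p = 5.86e-05), Cldn1 (-1.49 ± 0.12, adjusted p = 5.36e-04), Myh7 (-1.41 ± 0.09, adjusted p = 1.80e-04), Adh7 (-1.38 ± 0.22, adjusted p = 0.00844), Smpd3 (-1.38 ± 0.35, adjusted p = 0.0491) and Ckm (-1.25 ± 0.08, adjusted p = 2.38e-04). Myh7 and Ckm were not well above background on both arrays in the 2-injection pool, so their ratios are no exact sizes.

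Skeletal muscle genes were lower after 2 than after 1 injections, and a candidate explanation is muscle tissue in the 1-injection pool. The 22 tested muscle markers that had not been seen before had a median log2 ratio of -0.32, or -0.29 with 6 markers under background in the 2-injection pool at their bound, and 19 were below 0. The 13 markers called lower (5 seen before) were all called higher after 1 injection than in hypophysectomised males (median 0.90), and the 8 of them tested after 2 injections had a median of -0.077 (interquartile range 0.062) against -0.98 between the GH pools, which argues against more muscle in the hypophysectomised male pools beside the 2-injection pool as the whole difference. The brightest muscle probes in the 1-injection pool were those of Tpm1 (log2 level 11.82, log2 ratio 0.25 ± 0.10, adjusted p = 0.16), Eno3 (10.22) and Myl11 (9.01), levels that do not rank the genes by abundance, and 17 of the 30 markers on the array were measurable in intact livers. Limma called 0 of the 8 lower after 2 injections than in hypophysectomised males (0 at an unadjusted p under 0.05), but muscle gene expression in liver that rose with 1 injection and fell back to the untreated level would give this too, so it and muscle tissue cannot be told apart.

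Interferon responsive genes had a median log2 ratio of 1.00 between 2 and 1 injections, while the 25 tested lymphocyte and macrophage markers had one of -0.14 (interquartile range 0.27), which argues against more of these cells in the 2-injection pool. Background correction, normalization or dye may not be the whole of the difference, as the highest camera adjusted p with processed signals, median centring or no dye coefficient was 1.49e-13. Over all 8 alternatives it went from 1.38e-20 with median centring to 0.225 with an estimated correlation. They may account for a part, because the median fell to 0.73 with median centring, below the bound set beforehand. With 1 pool of 5 livers, the second GH injection and a state of these animals unrelated to GH cannot be told apart, and the later time after the first injection stays open, as untested.

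Cdh17 fell after 1 injection (-3.08 ± 0.14, adjusted p = 2.35e-05) and rose after 2 (2.34 ± 0.14), and the tables argue against 1 probe or array as the source, since its second probe, not the one the gene was chosen by, had -1.58 and 1.73 and 100% of the values of both probes on the 4 GH arrays had the direction of the mean. Intestinal epithelium in the intact pools is argued against by the other 12 tested intestinal markers, whose median between intact males and females was -0.075 (interquartile range 0.72) where Cdh17 had 6.98. That comparison holds no GH pool. After 1 injection the other 11 tested markers had a median of 0.044 (interquartile range 0.23). After 2 injections the other 14 had 0.010 (interquartile range 0.27). In the comparisons that per the labels used different pools, its 2 arrays differed by at most 0.586, which argues against unequal pools of those kinds. Each GH pool was measured alone, so a difference particular to either stays open. Control of Cdh17 by GH that depends on the number or the timing of injections may be a hypothesis to follow up.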

How the results depend on the processing

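The slide-1 counts of both GH comparisons, the reversal counted with females, and the slide block for gene lists and named genes were chosen only after seeing the data. Of 165 alternative counts for the comparisons, relations and lists, 100 stayed within 1.5 times the reported one and 65 did not. Aquantile normalization between arrays is left out of these, as it leaves every log ratio as it was and moved nothing. Replicate numbers were not used as pairs in the fit, while the simulations let arrays with the same number share RNA. The deviations of arrays with the same number had correlations of -0.67 to 0.84 over 15 pairs of comparisons (median -0.32, 6 of them over 0.1). Pairs with a shared RNA on the same side had 0.84, 0.69 and 0.38. With it on opposite sides they had -0.67 to 0.04, and pairs sharing no RNA had -0.53 to 0.41. Arrays with the same number may thus share pools, which the fit does not take into account.

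Median centring in place of loess gave 261 probes for the intact sexes, 345 for hypophysectomy in males (121 up, 224 down), 371 in females (143 up, 228 down), 7 for the hypophysectomised sexes, 0 for 1 GH injection (limma, 997 at an unadjusted p under 0.05), 75 for 2 injections, 157 for the sex dependence and 0 for 2 against 1 injections (limma, 476 at an unadjusted p under 0.05). It raised the median residual SD from 0.103 to 0.369 and moved the median of all probes to -0.13 for the intact sexes, 0.10 for hypophysectomy in males and -0.11 for the hypophysectomised sexes and 2 injections. It also gave 182 sex-biased probes changed by hypophysectomy, 9 responsive to GH and 20 hypophysectomy changes reversed by GH, and turned Lyve1 and Apob after 2 injections to -0.25 and -0.25, and Atp2a2 between the intact sexes to -0.035, the shifts of the median being -0.11 and -0.13.

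Without the dye coefficient the counts were 2603 (intact sexes), 83 (hypophysectomised sexes), 2106 (1 injection), 2036 (sex dependence), 1153 (2 against 1), and 2146, 1288 and 2518 for the 3 relations in the order above. With 1 coefficient per RNA group they were 6344 (intact sexes) and 1007 (hypophysectomised sexes). The hypophysectomised sexes had 393 without background correction (165 up, 228 down), 115 with processed signals, 114 with the value table, 143 with replicate blocks and 453 with slide blocks (the other 7 counts with replicate blocks stayed within 1.5 times the reported ones), and 2 against 1 injections had 4056 without background correction. The cause of these moves was not tested, and the cause was not tested either for median centring beyond the values given.

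From the arrays involved alone they were 2685 (hypophysectomy in males), 6 (hypophysectomised sexes), 812 (1 injection), 3675 (2 injections) and 2101 (sex dependence). Slide 1 alone gave higher counts, 12263, 14860 and 10723 for 1, 2 and 2 against 1 injections. Its fit holds no spread between slides or between GH pools, and the cause of the higher counts was not tested. A stricter threshold lowers the counts by construction, and an adjusted p of 0.01 gave 2091, 5688, 5155, 56, 1542, 5765, 1632 and 852, in the order of the counts with median centring. The estimates of the sex dependence gave 1212 and 1300 alone, and sex-biased probes at least 2-fold in both comparisons and responsive to GH numbered 169. Leaving out each array gave, in the same order, 1295 to 1446, 5647 to 8954, 3581 to 4160, 22 to 46, 558 to 629, 4183 to 4870, 1888 to 3852 and 461 to 955, the lone array being assumed to vary like the other groups. The sex dependence rose to 3852 without the first array of hypophysectomy in males, and the cause was not tested for any of these counts from fewer arrays.

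Among gene lists, camera with an estimated correlation called 0 of 200 tests (fry 84, camera with the preset correlation 77), and the cause was not tested. Other settings called 69 to 80. Of 6261 values of named genes, Aquantile again left out, 4871 kept their side of the threshold, 1387 lost the call in the same direction and 3 changed direction. The loop of 4 RNAs had 0 probes called by limma under every setting run (168 at an unadjusted p under 0.05 in the reported fit). Probes under background on both arrays of a comparison were not measured, which limits what the counts cover.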

Other observations

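The genes in this part were picked after their values were seen, and no test beyond those reported was run on them. The beta globin Hbb had a log2 ratio of -3.69 after hypophysectomy in males, -1.48 in females, and 2.45 and 1.54 after 1 and 2 GH injections in males, and Alas2, the heme synthesis enzyme of red cells, had -2.07, -0.96, 1.03 and 0.47. Between hypophysectomised males and females Hbb had -2.30. Of the 5 erythroid markers tested with hypophysectomy in males, 3 fell and 2 rose, and the list did not pass the camera test (adjusted p = 0.372). After GH the list did not follow Hbb and Alas2. Its 5 members had medians of -0.19 and -0.31 on the 2 arrays of 1 injection, and -0.59 and -0.64 on those of 2.

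Bcl6, a repressor, had a log2 ratio of 3.95 between intact males and females, 3.20 after hypophysectomy in females and -1.77 after 1 GH injection. Cux2 had -4.82 between the intact sexes, -3.79 after hypophysectomy in females, -1.65 between the hypophysectomised sexes, and 3.74 and 3.87 after 1 and 2 injections. Onecut1, which had -2.66 between the intact sexes, rose by 3.35 and 3.64 after 1 and 2 injections. The pantetheinase Vnn1 had 2.59 between the intact sexes and 2.64 after hypophysectomy in females.

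Utx, an X-linked histone demethylase gene, had -0.79, -0.35 and -0.66 on its 3 probes between intact males and females. The Y-linked Tspy and Hsfy1 were not above background there.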
